A study of Mus musculus with 399 samples.

How the data were processed

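The data were poly(A) RNA-seq libraries of 4 mouse tissues. Per the labels' protocols, RNA was extracted with a column kit, RNA integrity numbers were above 8, and stranded TruSeq libraries were made from 1000 ng of RNA. Per the submitters' processing notes, the tools named were Trimmomatic 0.39, HISAT2 2.2.1, SAMtools, DESeq and DESeq2 and the genome build was GRCm39. The read counter, its strand setting and the gene annotation are not given in the sources used here. Antisense and overlapping genes and near-identical copies therefore carry uncertain values.

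The deposited count tables hold whole-number counts of reads per Ensembl gene, not normalized, and were the source of every test. The deposited normalized tables hold, as a signal value, the authors' counts divided by a library factor. In 4 libraries that were checked, this factor matched the median-of-ratios factor over 8823 genes counted in every library of the series. In the deposited FPKM tables the FPKM values were the normalized values divided by a constant per gene. Neither normalized table was used further. Gene symbols came from a GENCODE M21 annotation on GRCm38, used for names and for gene GC content and not for coordinates: 52073 of 56980 identifiers had a symbol.

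Samples were grouped by the labels into tissue, sex, strain, diet and age, 64 groups of 5 to 10 mice. The labels give each library an animal, and 74 animal labels occur in fat, liver and soleus. Library totals had medians of 11235896 in liver, 7773866 in fat, 11488613 in soleus and 6559752 in pancreas, where the 10 most counted genes took a median of 64.6% of the reads.

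Each tissue was fitted on its own with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). The model had 1 mean for each of the 16 groups, TMM factors, and genes kept by filterByExpr (minimum count 10, minimum total 15). Quasi-likelihood F tests gave 9 contrasts per tissue, 36 in all, with the Benjamini-Hochberg adjustment over the genes of a contrast and a threshold of 0.05. Standard errors are the fold change divided by the square root of F. Strain is TH minus B6, diet high-fat minus chow, sex male minus female, and age 20 minus 5 weeks. Sexes were averaged in strain, diet and age contrasts, and strains in sex, age and 5-week diet contrasts. The interactions are the TH minus the B6 diet response and the male minus the female strain difference.

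The design, the alternatives, 32 gene lists of pathways and cell types and the rule for named genes were fixed before the data were examined. For strain on chow at 20 weeks and for diet in each strain, the rule took the 5 called genes with the largest rise and the 5 with the largest fall. For other contrasts it took 3 of each. It required a mean log2 CPM of at least 1 and, except for strain by sex, sex and age, the same sign in both sexes, and it left out predicted, clone and pseudogene names. Not every gene it took is named. Members of the lists were named in their tissues. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a contrast. The contrast of diet by sex within TH was added after the data were seen.

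Alternatives were RLE factors, no filter on low counts, DESeq2 1.42.0 with its Wald test, a fit of only the groups compared, the replicate number as a block, and leaving out each of the 5 mice of the soleus group of that size. Added after the data were seen were the slope of each library's log2 CPM on gene GC content as a covariate, scores of epididymis and of ovary and uterus markers as covariates in fat, and a fit without libraries whose deviation from the group mean exceeded 2 times the tissue median. These were 6 male fat libraries (at 20 weeks B6 chow 4, B6 high-fat 3 and TH high-fat 1, at 5 weeks B6 high-fat 3, TH chow 2 and TH high-fat 1), soleus B6 female high-fat 5 at 5 weeks and pancreas TH female chow 4 at 20 weeks. For other splits, 40 assignments of the compared samples were drawn per contrast in a fit of only those samples.

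The steps were tested on simulated data with 200 genes changed for diet in TH. At a log2 change of 1 the liver fit of 16924 genes found 88 of 98 and at 0.5 it found 64 of 98, with 13 unchanged genes among 168 calls. The fat fit of 19226 genes found 74 of 95 and 36 of 97, with 16 unchanged among 127. In each tissue camera called only the shifted list, which leaves correlated genes untested. Tables and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.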

Results

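The series measured transcripts in liver, gonadal fat, soleus (a postural leg muscle rich in slow fibres) and pancreas of 2 inbred mouse strains, TH (TALLYHO/Jng) and B6 (C57BL/6J). TH is a strain used as a model of obesity and type 2 diabetes, and B6 was its comparison strain. Male and female mice received chow or a high-fat diet from weaning at 4 weeks and were sampled at 5 or 20 weeks, after 1 or 16 weeks of feeding. The libraries (96 of liver, 96 of fat, 97 of soleus and 110 of pancreas) fell into 64 groups of 5 to 10 mice by tissue, sex, strain, diet and age. Values after a gene symbol are log2 fold changes ± standard error from the edgeR quasi-likelihood test, averaged over both sexes unless stated, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Where camera, with its preset correlation of 0.01, called a list, its adjusted p with an estimated correlation is given, and lists without such a p were not called. Counts over the list alone adjust p over its members. Brackets after a list count give the lowest and highest number of members called, up or down, by alternative fits that moved it by over 1.5 times: no low-count filter (no filter), only the groups compared (groups only), replicate block (block), RLE factors (RLE), DESeq2, each library's GC slope (GC), without deviating libraries (trimmed) and neighbouring tissue scores (neighbours).

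Xist, the RNA that coats the inactive X chromosome, and the Y-linked Ddx3y, Uty, Eif2s3y and Kdm5d matched the labelled sex in every library. Alb, Adipoq, Myh7 and Prss2, the markers chosen for liver, fat, soleus and pancreas, matched the labelled tissue in every library. Nnt, which carries a known deletion in C57BL/6J, was low in both strains. In soleus it stood at 8.54 ± 4.35 CPM (SD, n = 48) in TH and 3.84 ± 1.91 CPM (SD, n = 49) in B6. Its ranges overlapped in every tissue, so as a check of the strain label it was void.

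Liver of TH mice on chow at 20 weeks was compared with B6 to ask how the strains differ without a dietary challenge (12 TH and 12 B6 mice). Inflammatory transcripts were lower in TH: 16 of 21 macrophage genes, among them Itgax (-1.78 ± 0.42) and Fcer1g (-1.50 ± 0.16), and 15 of 18 interferon-response genes, among them Rtp4 (-2.03 ± 0.27) and Isg15 (-1.31 ± 0.34). Fatty acid oxidation genes were lower for 12 of 23 members, led by the PPARα targets Cyp4a14 (-5.59 ± 0.46) and Vnn1 (-4.58 ± 0.27). Lipid droplet genes were lower for 6 of 12, including Pparg (-3.62 ± 0.24), a regulator of fat storage, and the fatty acid transporter Cd36 (-1.88 ± 0.23). Endoplasmic reticulum chaperones of the unfolded protein response were higher for 10 of 21, such as Hyou1 (0.95 ± 0.19) and Hspa5 (0.57 ± 0.13). For macrophage, interferon response, fatty acid oxidation and lipid droplet genes the counts were 16, 16, 12 and 6 over the list alone, and camera gave adjusted p = 0.958 for each. For unfolded protein response genes it was 12 over the list alone.

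In the same comparison 7268 of 17243 genes were called, 3660 higher and 3608 lower in TH, 1340 of them by at least 2-fold. The largest excesses in TH were Ren1 (8.38 ± 0.60), which encodes renin, the chemokine receptor Ccr3 (6.55 ± 0.40), the aspartic protease Ctse (6.33 ± 0.24), the ABC transporter Abcc12 (5.55 ± 0.31) and the ion channel Trpv1 (5.03 ± 0.29). The largest deficits were C1s1 (-8.88 ± 0.23), a complement protease gene, Ugt2b5 (-7.41 ± 0.21), Acpp (-6.67 ± 0.34), Camk2b (-6.54 ± 0.42) and Btnl9 (-6.19 ± 0.26). C1s1 and Ugt2b5 have close paralogs, so their values depend on how shared reads were assigned.

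High-fat feeding for 16 weeks was tested in B6 liver (12 high-fat and 12 chow mice). Genes of fatty acid synthesis rose for 13 of 19, including the fatty acid synthase Fasn (1.28 ± 0.25), the elongase Elovl6 (1.27 ± 0.25) and Pnpla3 (5.09 ± 0.54), a lipase-like gene of the lipogenic programme. Cholesterol synthesis genes fell, 17 of 25, among them Msmo1 (-1.23 ± 0.17). Fatty acid oxidation genes fell for 15 of 23, such as Cyp4a14 (-3.00 ± 0.39) and Angptl4 (-1.41 ± 0.23), whereas the hormone gene Fgf21 (2.32 ± 0.70) rose. Macrophage genes rose for 13 of 21, with Itgax (1.01 ± 0.30) and Lgals3 (0.94 ± 0.24), and interferon-response genes for 15 of 18, with Ifi44 (1.79 ± 0.33) and Oas1a (1.36 ± 0.23). For de novo lipogenesis, cholesterol synthesis, fatty acid oxidation, macrophage and interferon response genes the counts were 15, 19, 16, 13 and 16 over the list alone, and camera gave adjusted p = 0.109, 0.298, 0.109, 0.334 and 0.298.

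In B6 liver 4059 genes were called, 2055 up and 2004 down, and 377 changed by at least 2-fold. Besides Pnpla3, the largest rises were the N-acetyltransferase genes Nat8f7 (3.83 ± 0.42), Nat8f3 (3.25 ± 0.39) and Nat8f6 (3.18 ± 0.42) and the male-biased steroid enzyme Hsd3b5 (3.29 ± 0.45). Falls were led by the xenobiotic enzyme Cyp2b10 (-5.74 ± 0.33), the glutathione transferases Gsta1 (-4.16 ± 0.42) and Gsta2 (-3.995 ± 0.33), and the noncoding Snhg11 (-3.21 ± 0.21) and Rian (-3.12 ± 0.29). The Nat8f and Gsta genes are close paralogs whose reads cannot be fully separated here.

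The same diet in TH liver (12 high-fat, 12 chow) raised 15 of 19 fatty acid synthesis genes, including Fasn (1.97 ± 0.26), Elovl6 (2.25 ± 0.26) and the desaturase Scd1 (2.08 ± 0.27). Cholesterol synthesis genes fell for 21 of 25, with Sqle (-1.36 ± 0.24) and Hmgcs1 (-1.10 ± 0.18). Collagen and other matrix genes rose for 16 of 20, including Col1a1 (1.45 ± 0.23) and Col3a1 (1.24 ± 0.17), and macrophage genes for 17 of 21, including Gpnmb (1.67 ± 0.55) and Itgax (1.70 ± 0.41). Of the cell proliferation genes 9 of 22 rose, such as Mki67 (1.75 ± 0.43) and Ccnb1 (1.85 ± 0.68). Of the glucose metabolism genes 8 of 16 rose and 3 fell, with glucose-6-phosphatase G6pc (0.95 ± 0.25) up and Pck1 (-0.67 ± 0.16) down. Bile acid genes fell for 6 of 15, including Cyp7a1 (-0.95 ± 0.33), the rate-limiting enzyme of bile acid synthesis. For de novo lipogenesis, cholesterol synthesis, extracellular matrix, macrophage, cell proliferation, glucose metabolism and bile acid genes the counts were 17, 21, 17, 19, 9, 10 up and 4 down and 9 over the list alone, and camera gave adjusted p = 0.0176, 0.164, 0.174, 0.226, 0.492, 0.351 and 0.226.

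TH liver showed 4531 called genes, 2181 of them down, and 577 changed by at least 2-fold. The strongest rises beside Pnpla3 (5.45 ± 0.56) were Fam198a (4.87 ± 0.34), the hormone gene Fgf21 (3.67 ± 0.47) and the pancreatic amylase copy Amy2a5 (3.68 ± 1.45, adjusted p = 0.0480), which is near-identical to other copies. Falls were led by Cyp2b10 (-5.77 ± 0.30), the metallothioneins Mt1 (-3.58 ± 0.51) and Mt2 (-4.32 ± 0.66), and the transferase copies Gsta1 (-3.56 ± 0.44) and Gsta2 (-4.24 ± 0.36). Both strains shared 841 rises and 1002 falls, where independent lists would share at most 280.1. In high-fat TH males Col1a1 stood at 26.6 ± 20.8 CPM (SD, n = 6), against 4.77 ± 1.17 CPM (SD, n = 6) on chow. Of the circadian clock genes 3 of 16 rose and 7 fell, with Dbp (-2.81 ± 0.72) lower and Npas2 (2.01 ± 0.39) higher. For circadian clock genes the count was 4 up and 7 down over the list alone.

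**Figure D1:**
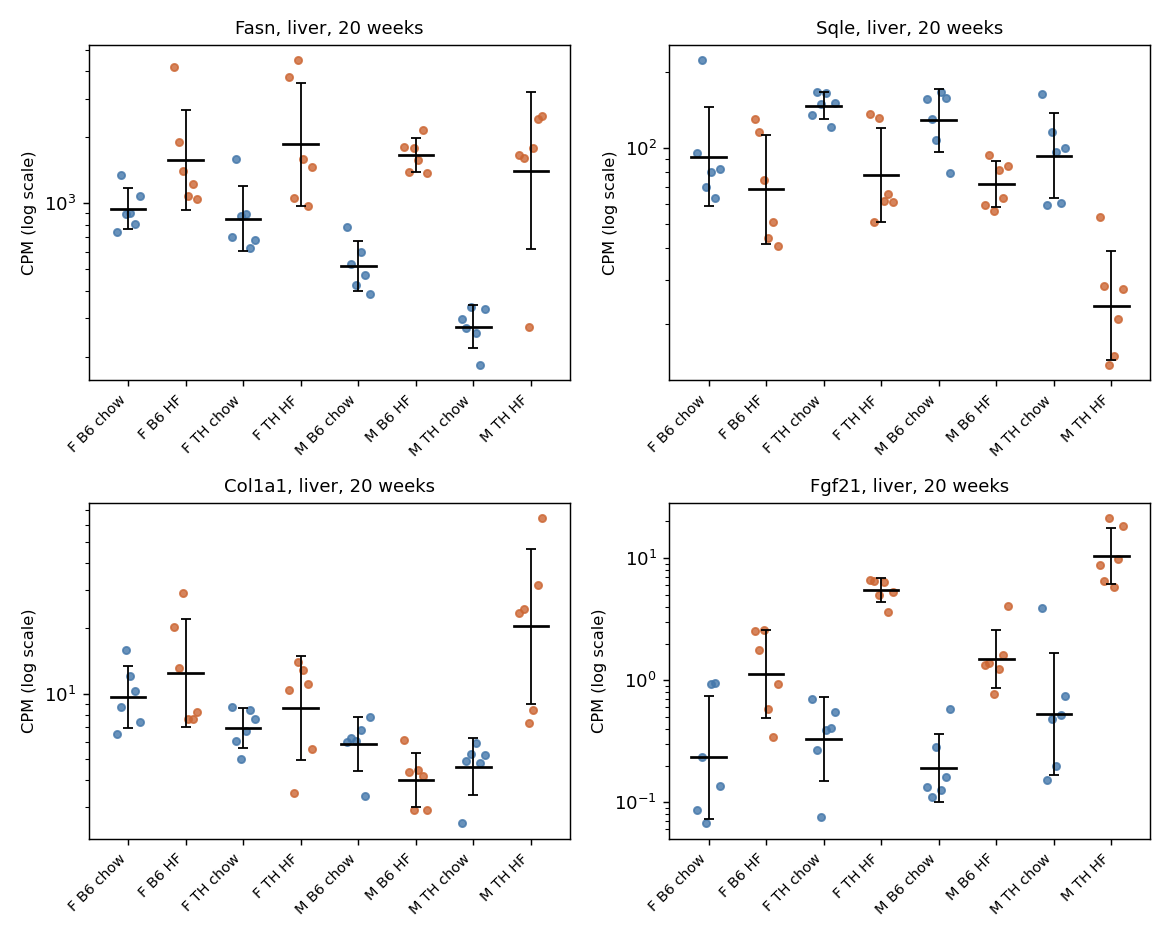
CPM (log axis) of Fasn, Sqle, Col1a1 and Fgf21 in each liver library at 20 weeks, by sex (F, M), strain and diet (chow or HF, high-fat). Lines are geometric means and bars the SD of log2 values.

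Whether the 20-week diet response differed between strains was tested directly in liver as the TH response minus the B6 response. Matrix genes had a higher TH than B6 response for 7 of 20, led by Col1a1 (1.45 ± 0.34) and Col1a2 (1.08 ± 0.25). So did 5 of 23 fatty acid oxidation genes, with Vnn1 (2.61 ± 0.34) and Pdk4 (2.37 ± 0.36), a brake on glucose oxidation, and 4 of 19 lipogenesis genes (2 no filter), with Scd1 (1.55 ± 0.37) and Acacb (1.44 ± 0.42). The fatty acid transporter Cd36 (1.45 ± 0.32) was the lipid droplet gene called, 1 of 12 (2 no filter). In all 677 genes were called (345 above 0 and 332 below), led by Fam198a (3.61 ± 0.44), Vnn1 and Prom1 (2.56 ± 0.60) above and by Ly6a (-3.18 ± 0.44), Kcnk10 (-1.76 ± 0.32) and Bmf (-1.73 ± 0.45) below. With no filter on low counts the number was 443. For extracellular matrix, fatty acid oxidation, de novo lipogenesis and lipid droplet genes the counts were 13, 7, 7 and 2 over the list alone, and camera gave adjusted p = 0.308, 0.308, 0.647 and 0.308.

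The strain difference on chow was compared between sexes as the male difference minus the female difference. Male-biased liver genes had a lower male than female strain difference for 5 of 16, among them Hsd3b5 (-3.18 ± 0.99) and Cyp4a12a (-2.90 ± 0.80), whose copy Cyp4a12b is near-identical. Chaperone genes followed for 3 of 21 (0 groups only, 1 no filter), with Hyou1 (-1.21 ± 0.37) and Manf (-1.13 ± 0.36). Across 851 called genes (285 above 0, 566 below), the largest values were those of Mt2 (4.66 ± 1.13), Rad51b (4.60 ± 1.05) and the clock gene Npas2 (4.15 ± 0.91), and the lowest those of Ugt2b37 (-4.97 ± 0.46), Nat8f6 (-3.86 ± 1.01) and Susd4 (-3.21 ± 0.31). A fit of only the groups compared called 283. For male-biased liver and unfolded protein response genes the counts were 7 and 7 over the list alone, and camera gave adjusted p = 0.440 for each.

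At 5 weeks the liver strain comparison (12 TH, 12 B6) again had lower macrophage transcripts in TH, 15 of 21, and lower interferon-response transcripts, 13 of 18, with Itgax (-1.31 ± 0.38) and Rtp4 (-1.41 ± 0.26). Male-biased liver genes were higher in TH for 10 of 16, such as Cyp4a12a (3.46 ± 0.33) and the terminal complement gene C6 (3.17 ± 0.18). Female-biased genes were lower for 9 of 18 and higher for 3, with Cyp17a1 (-2.85 ± 0.30) and Cyp2b9 (-2.58 ± 0.37) lower. Of 6734 called genes 2489 were lower in TH at both ages, where independent lists would share 730.3. The extremes were Apol10a (6.64 ± 1.12), Ren1 (6.11 ± 0.43) and Ctse (6.03 ± 0.23) above, and C1s1 (-9.09 ± 0.24), Acpp (-7.85 ± 0.44) and Ugt2b5 (-7.17 ± 0.21) below. For macrophage, interferon response and male-biased liver genes the counts were 15, 13 and 12 over the list alone, and camera gave adjusted p = 0.770 for each. For female-biased liver genes it was 4 higher and 9 lower over the list alone.

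A single week of high-fat feeding, tested over both strains and sexes in liver (24 high-fat, 24 chow), lowered 25 of 25 cholesterol synthesis genes, with Sqle (-1.74 ± 0.18) and Idi1 (-1.66 ± 0.15) lowest. Macrophage genes rose for 12 of 21, including the lipid-associated receptor Trem2 (1.68 ± 0.22) and the elastase Mmp12 (2.05 ± 0.55). Female-biased genes fell for 8 of 18, and bile acid genes for 5 of 15, with Cyp7a1 (-1.61 ± 0.23). The 4007 called genes (1859 up, 2148 down) were led by Fgf21 (3.51 ± 0.56), the apolipoprotein Apoa4 (2.51 ± 0.14) and Ttbk1 (2.43 ± 0.20). The lowest were Cyp2b10 (-5.80 ± 0.20) and the skeletal muscle transcripts Myh1 (-7.18 ± 2.17) and Atp2a1 (-5.85 ± 1.58). For cholesterol synthesis, macrophage, female-biased liver and bile acid genes the counts were 25, 13, 8 and 5 over the list alone, and camera gave adjusted p = 0.00298, 0.485, 0.485 and 0.310.

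Males were compared with females on chow at 20 weeks over both strains (12 and 12 mice). In liver all 16 male-biased genes were higher in males, such as Elovl3 (6.90 ± 0.45) and Mup20 (6.16 ± 0.23), and 16 of 18 female-biased genes were lower. Chaperones of the unfolded protein response were higher in males for 17 of 21, with Hspa5 (1.00 ± 0.13) and Dnajb9 (1.15 ± 0.18). Matrix genes were lower in males for 13 of 20 (9 GC) and interferon-response genes for 11 of 18 (3 GC), with Col1a1 (-0.65 ± 0.25) and Ifi44 (-1.59 ± 0.42). Among the extremes of 7684 called genes were the Y-linked Eif2s3y (10.91 ± 0.22), Ddx3y (10.80 ± 0.21) and Uty (9.39 ± 0.22) and the female-biased Sult3a1 (-11.47 ± 0.50) and Sult2a1 (-10.09 ± 0.68). For male-biased liver, female-biased liver, unfolded protein response, extracellular matrix and interferon response genes the counts were 16, 16, 17, 15 and 12 over the list alone, and camera gave adjusted p = 9.05e-06, 1.56e-04, 0.144, 0.680 and 0.767.

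Growth from 5 to 20 weeks on chow was compared over both strains (24 mice at 20 and 24 at 5 weeks). In liver 19 of 22 cell proliferation genes fell with age, with Cdc20 (-2.21 ± 0.39) and Mki67 (-1.44 ± 0.30), and 14 of 20 matrix genes fell, with Col1a1 (-1.58 ± 0.16) and Sparc (-1.38 ± 0.09). Fatty acid oxidation genes rose for 11 of 23, led by Pdk4 (1.42 ± 0.19), and interferon-response genes fell for 12 of 18. Among 3720 called genes (1604 up, 2116 down) Srgap3 (3.01 ± 0.24) and Serpine2 (2.10 ± 0.15) were among the largest rises. The fetal RNA-binding protein gene Igf2bp3 (-5.03 ± 0.16), the muscle calcium pump gene Atp2a1 (-3.38 ± 1.29, adjusted p = 0.0460) and Pls1 (-2.70 ± 0.17) fell most. For cell proliferation, extracellular matrix, fatty acid oxidation and interferon response genes the counts were 20, 15, 13 and 14 over the list alone, and camera gave adjusted p = 0.307, 0.00463, 0.307 and 0.448.

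In gonadal fat on chow at 20 weeks, TH (12 mice) was compared with B6 (12 mice). Macrophage genes were higher in TH for 14 of 21, led by Mmp12 (5.39 ± 0.54), Gpnmb (2.54 ± 0.42) and Itgax (2.36 ± 0.36), and T cell genes for 6 of 11, such as Cd4 (1.74 ± 0.29). In male TH fat Gpnmb, a glycoprotein of lipid-laden macrophages, stood at 650.3 ± 435 CPM (SD, n = 6), against 20.0 ± 4.54 CPM (SD, n = 6) in male B6 and 16.1 ± 13.8 CPM (SD, n = 6) in female TH. Lipogenesis genes were lower for 11 of 19, with Acaca (-1.28 ± 0.26) and Fasn (-0.87 ± 0.28), and oxidative phosphorylation genes for 12 of 42 (20 GC, 22 trimmed/neighbours), with Sdhc (-0.62 ± 0.11). Matrix genes were higher for 11 of 21, with Timp1 (1.204 ± 0.33) and Col6a1 (1.02 ± 0.18). Of the mature adipocyte genes 6 of 15 were higher and 3 lower, with leptin Lep (2.03 ± 0.26) and the expansion-associated Sfrp5 (3.77 ± 0.36) and Mest (2.43 ± 0.33) higher. For macrophage, T cell, de novo lipogenesis, oxidative phosphorylation and extracellular matrix genes the counts were 16, 8, 12, 12 and 13 over the list alone, and camera gave adjusted p = 0.556, 0.685, 0.685, 0.756 and 0.685. For mature adipocyte genes it was 6 higher and 3 lower over the list alone.

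Interferon-response genes were lower in TH fat for 7 of 18, with Isg15 (-1.05 ± 0.30). Of 19715 genes tested 5232 were called, 2515 higher and 2717 lower, 1504 of them by at least 2-fold. Beside Mmp12, TH excesses were greatest for the interferon-inducible Ifi202b (8.32 ± 0.39), the ribonuclease Rnase2a (7.40 ± 0.45), the histidine-degrading enzyme Hal (6.49 ± 0.33) and B4galnt2 (5.31 ± 0.59). Deficits were greatest for St6galnac5 (-8.67 ± 0.64), C1s1 (-8.02 ± 0.21), Atp10b (-6.60 ± 2.35), Cwh43 (-6.60 ± 1.38) and Cyp2f2 (-6.20 ± 0.29). Without the 6 fat libraries that lay far from their groups, Atp10b and Cwh43 were not called (adjusted p = 0.629 and 0.549). For interferon response genes the count was 7 over the list alone, and camera gave adjusted p = 0.756.

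**Figure D2:**
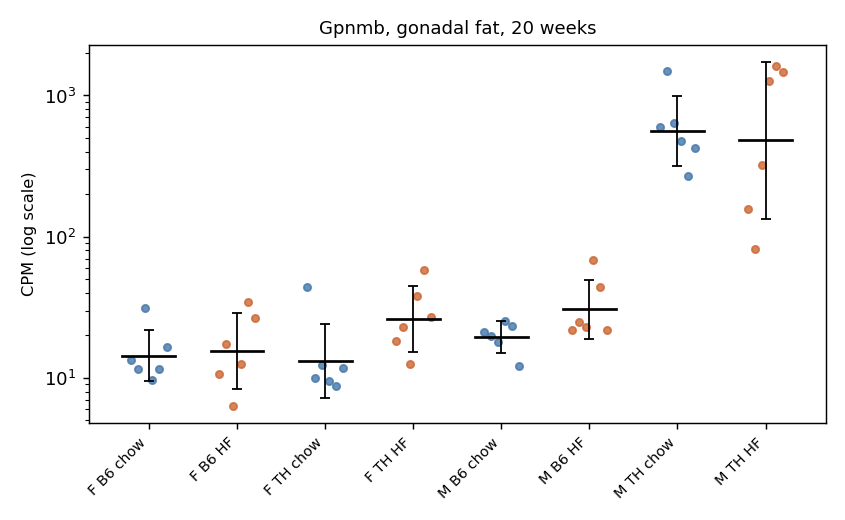
Gpnmb CPM (log axis) in each gonadal fat library at 20 weeks by sex, strain and diet. Lines are geometric means and bars the SD of log2 values. The chow TH males lie between 267.1 and 1497 CPM, above every B6 library.

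High-fat feeding for 16 weeks in B6 fat (12 high-fat, 12 chow) raised interferon-response genes for 6 of 18 (3 trimmed), with Isg15 (0.97 ± 0.26) and Oas1a (1.10 ± 0.23). Circadian clock genes fell for 9 of 16, with Dbp (-2.09 ± 0.39) and Per2 (-1.29 ± 0.25), while Arntl (0.86 ± 0.23), their activator, rose. Macrophage genes were called higher for 2 of 21 (0 no filter/neighbours, 6 DESeq2), and mature adipocyte genes for 3 of 15, with Lep (0.89 ± 0.26) and Mest (1.59 ± 0.32). The 592 called genes (333 up, 259 down) were led by liver-type secreted proteins, Mup20 (4.20 ± 0.60), Fgb (4.14 ± 0.54), Gc (3.98 ± 0.89), Mug1 (3.96 ± 0.50) and Pzp (3.87 ± 0.56). The Mup genes are near-identical copies. Falls were led by Cwh43 (-8.13 ± 1.59), Trpv6 (-6.15 ± 1.45), Ltf (-6.09 ± 1.48), Npy (-5.85 ± 1.66) and Wfdc2 (-5.06 ± 1.32). Without the deviating libraries none of these 5 falls was called by edgeR (Cwh43 fell by 3.89, adjusted p = 0.582), nor was Isg15. For interferon response, circadian clock, macrophage and mature adipocyte genes the counts were 14, 9, 16 and 3 over the list alone, and camera gave adjusted p = 0.0701, 0.0701, 0.0904 and 0.508.

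The same diet in TH fat (12 high-fat, 12 chow) left 39 genes called over both sexes, 4 up and 35 down. Within males 695 were called (1188 in a fit of only the groups compared, 1094 without the deviating libraries, 357 with no filter on low counts) and within females 2 (71 with DESeq2). Cfd (-1.35 ± 0.27), the adipocyte protease adipsin, fell, and it was the mature adipocyte gene called of 15. The clock repressor Nr1d1 (-1.06 ± 0.25) fell as the circadian gene called of 16 (0 no filter, 3 groups only/DESeq2). Unc5a (1.56 ± 0.38) and the stress gene Gadd45a (0.77 ± 0.18) rose, and Slc38a3 (-1.66 ± 0.40) fell. Epididymis markers had a median of 3.63, carried by high-fat male replicates 1 and 3, of which 3 was not among the deviating libraries. Without the deviating libraries 145 genes were called. For mature adipocyte and circadian clock genes the counts were 6 and 6 over the list alone, and camera gave adjusted p = 0.192 for each.

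The TH minus B6 difference in the fat diet response was called for 85 genes, 8 above 0 and 77 below. The adipocyte genes Sfrp5 (-2.06 ± 0.48) and Mest (-1.87 ± 0.44) had a lower TH than B6 response, 2 of 15 mature adipocyte genes (0 neighbours, 1 trimmed). Below 0 also lay the liver-type secreted proteins Mup20 (-4.001 ± 0.84), Apoa1 (-3.76 ± 0.76) and Mug1 (-3.76 ± 0.79). Dpp6 (5.21 ± 1.28), Cyp2f2 (2.44 ± 0.50) and Mamld1 (1.10 ± 0.28) lay above 0. Without the deviating libraries 49 genes were called, but not Sfrp5, Dpp6 or Mamld1. For mature adipocyte genes the count was 4 over the list alone, and camera gave adjusted p = 0.311.

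In fat 7 of 21 macrophage genes had a higher male than female strain difference (4 no filter), including Gpnmb (4.95 ± 0.83), Itgax (3.80 ± 0.71) and Atp6v0d2 (7.00 ± 1.25). B and plasma cell genes ran the other way for 4 of 12 (2 groups only), such as Ms4a1 (-2.92 ± 0.59). Of 321 called genes (185 above 0, 136 below), the Mup copy Mup18 (6.43 ± 1.06) was among the highest, and Fosb (-3.10 ± 0.68) and Cxcl13 (-2.95 ± 0.59) among the lowest. Without the deviating libraries 1162 were called. For macrophage and B and plasma cell genes the counts were 8 and 7 over the list alone, and camera gave adjusted p = 0.737 and 0.650.

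At 5 weeks fat of TH (12 mice) exceeded B6 (12) in 6 of 15 mature adipocyte genes, with Sfrp5 (4.30 ± 0.45) and Lep (1.90 ± 0.26). Mesothelial genes, which mark the serosal lining, were higher for 6 of 8 (3 neighbours), with Msln (1.498 ± 0.28), and matrix genes for 9 of 21 (4 neighbours, 14 trimmed), with Timp1 (1.12 ± 0.31). Interferon-response genes were lower for 9 of 18, with Isg15 (-1.34 ± 0.25). Of 4712 called genes 1194 were higher and 1417 lower at both ages, where independent lists would share at most 385. Ifi202b (7.89 ± 0.37), Rnase2a (7.27 ± 0.42) and Hal (5.02 ± 0.32) were the extremes above, and St6galnac5 (-9.09 ± 0.67), C1s1 (-7.99 ± 0.21) and Gabrp (-7.17 ± 1.88) below. For mature adipocyte, mesothelial, extracellular matrix and interferon response genes the counts were 7, 6, 12 and 10 over the list alone, and camera gave adjusted p = 0.771 for each.

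After 1 week of feeding the fat of 24 high-fat mice differed from 24 chow mice in 15 genes. The xenobiotic enzyme Cyp2f2 (-2.04 ± 0.24), Lrtm1 (-1.13 ± 0.21) and the paraoxonase Pon1 (-1.04 ± 0.20) fell, and the imprinted Zim1 (1.01 ± 0.19) and the inositol transporter Slc5a3 (0.59 ± 0.13) rose. The interferon regulator Irf7 (0.50 ± 0.11) was the interferon-response gene called over all genes, 1 of 18 (0 no filter/groups only, 2 DESeq2/trimmed/neighbours). For interferon response genes the count was 11 over the list alone, and camera gave adjusted p = 0.0417.

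Over both strains, male fat (12 mice) exceeded female (12) in 11 of 21 macrophage genes, with Mmp12 (4.92 ± 0.55), Gpnmb (2.84 ± 0.42) and Itgax (2.70 ± 0.36). Gpnmb differed by sex in TH, but B6 sexes overlapped. All 6 erythrocyte genes, which report blood in the tissue, were higher in males, with Alas2 (1.48 ± 0.30), and 4 of 12 immediate early genes, with Fos (1.16 ± 0.31). Lipogenesis genes were lower in males for 9 of 19, with Elovl6 (-2.40 ± 0.33) and Acly (-1.61 ± 0.28), and mesothelial genes for 6 of 8, with Wt1 (-1.64 ± 0.24). Of the epididymis genes 4 of 14 were higher in males (1 trimmed), with Crisp1 (7.34 ± 1.62). Of the ovary and uterus genes 2 of 7 were higher and 2 lower (2 groups only), with the granulosa cell gene Foxl2 (-3.36 ± 1.09) lower. Among 2927 called genes Sult1e1 (9.92 ± 0.53), Ddx3y (9.43 ± 0.33) and Uty (9.42 ± 0.40) were highest and Xist (-9.24 ± 0.35), Rxfp1 (-8.13 ± 0.94) and Pcp4 (-7.25 ± 0.92) lowest. For macrophage, erythrocyte, immediate early, de novo lipogenesis and mesothelial genes the counts were 15, 6, 6, 9 and 8 over the list alone, and camera gave adjusted p = 0.132, 0.132, 0.191, 0.343 and 0.132. For epididymis and ovary and uterus genes they were 4 and 2 higher and 2 lower over the list alone.

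From 5 to 20 weeks fat gained lymphocyte transcripts (24 and 24 mice): 11 of 12 B and plasma cell genes rose, with Jchain (2.03 ± 0.27) and Cd79a (1.26 ± 0.23), and 10 of 11 T cell genes, with Cd8a (1.46 ± 0.30) and Cd3e (1.26 ± 0.18). Macrophage genes rose for 20 of 21 (13 neighbours), with Mmp12 (1.69 ± 0.52) and Trem2 (1.52 ± 0.23). Cell proliferation genes fell for 19 of 22, with Cdc20 (-1.64 ± 0.23), and matrix genes for 13 of 21, with Col3a1 (-0.97 ± 0.17). The 5566 called genes (2745 up, 2821 down) were led by the adipocyte regulator Klf14 (3.48 ± 0.22), Prr32 (3.47 ± 0.22) and Mup20 (3.45 ± 0.77). Falls were led by the epididymis transcripts Adam28 (-6.10 ± 2.44, adjusted p = 0.0488), Teddm1a (-5.82 ± 2.19) and Lcn8 (-5.57 ± 1.79), beside 7 of 14 epididymis markers (1 neighbours, 12 DESeq2). Adam28 was not called without the deviating libraries (adjusted p = 0.0685). For B and plasma cell, T cell, macrophage, cell proliferation, extracellular matrix and epididymis genes the counts were 12, 11, 20, 19, 14 and 9 over the list alone, and camera gave adjusted p = 0.0277, 0.0408, 0.0790, 0.0998, 0.263 and 0.409.

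Soleus of TH mice (12) was compared with B6 (12) on chow at 20 weeks. Fast-fibre genes were lower in TH for 13 of 14, with Actn3 (-2.05 ± 0.36), Myh4 (-1.52 ± 0.37) and Pvalb (-1.51 ± 0.28). Of the slow-fibre genes 4 of 12 were higher and 1 lower, with Myh7 (0.30 ± 0.07), the slow myosin heavy chain, and Myh7b (1.54 ± 0.20) higher. Oxidative phosphorylation genes were lower for 34 of 42, with Sdhc (-0.67 ± 0.11) and Cox4i1 (-0.58 ± 0.13). Of the muscle atrophy genes 4 of 16 were higher and 4 lower (5 GC), with the ubiquitin ligase Fbxo30 (1.24 ± 0.36) higher. Of 17520 genes 8725 were called, 4834 higher and 3891 lower in TH, 2212 by at least 2-fold. For fast fibre and oxidative phosphorylation genes the counts were 13 and 35 over the list alone, and camera gave adjusted p = 0.194 and 0.903. For slow fibre and muscle atrophy genes they were 4 higher and 1 lower and 4 higher and 4 lower over the list alone.

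The largest TH excesses in soleus were B4galnt2 (8.79 ± 0.31), a glycosyltransferase of neuromuscular junctions, the cone opsin gene Opn1mw (5.85 ± 0.29), Fam184b (4.15 ± 0.27), Hirip3 (3.64 ± 0.15) and Pianp (3.50 ± 0.18). Deficits were largest for C1s1 (-8.02 ± 0.24), the mitotic securin gene Pttg1 (-5.88 ± 0.15), Eps8l1 (-5.67 ± 0.43), Pcp4l1 (-4.84 ± 0.18) and Fbxo44 (-4.48 ± 0.16). With each library's slope of expression on gene GC content as a covariate, 5238 genes were called in this contrast, and 14 of 14 fast-fibre genes were lower.

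In B6 soleus, 16 weeks of high-fat feeding (12 and 12 mice) left 23 genes called, 11 up and 12 down. The class I antigen-presentation genes H2-Q7 (1.39 ± 0.28), H2-Q6 (1.36 ± 0.30) and H2-Q10 (0.95 ± 0.21), which are close paralogs, rose with Chst11 (0.72 ± 0.17). Interferon-response genes had a median of 0.81, with 0 of 18 called by the reported edgeR fit over all genes (1 DESeq2, 7 groups only). Sec1 (-1.10 ± 0.23) and Ntn5 (-0.76 ± 0.18) fell. Of all genes 1949 had an unadjusted p under 0.05. For interferon response genes the count was 17 over the list alone, and camera gave adjusted p = 0.0257.

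High-fat feeding in TH soleus (12 high-fat, 12 chow) was called for 11917 of 17520 genes, 5764 up and 6153 down. This number moved when each library's slope of expression on gene GC content was a covariate. Oxidative phosphorylation genes rose for 31 of 42 (11 GC), with Cyc1 (0.77 ± 0.12) and Cox4i1 (0.76 ± 0.13), and macrophage genes for 11 of 18 (6 GC), with Trem2 (1.54 ± 0.36) and C1qa (1.33 ± 0.22). Of the muscle atrophy genes 8 of 16 fell and 4 rose (6 GC), with Fbxo32 (-0.88 ± 0.24), the ubiquitin ligase atrogin-1, and Foxo3 (-0.64 ± 0.12) lower. Mature adipocyte genes rose for 9 of 14, with Adipoq (1.26 ± 0.29) and Cidec (1.15 ± 0.27). The named extremes were the noncoding Rn7s6 (1.59 ± 0.27), Cgref1 (1.59 ± 0.25) and Cyp1a1 (1.48 ± 0.38) above, and Olfr558 (-1.84 ± 0.47), Zfp729a (-1.76 ± 0.47), Olfr78 (-1.73 ± 0.46) and Trp53inp1 (-1.66 ± 0.53) below. For oxidative phosphorylation and macrophage genes the counts were 31 and 11 over the list alone, and camera gave adjusted p = 0.638 for each. For muscle atrophy and mature adipocyte genes they were 4 up and 8 down and 9 over the list alone.

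Across genes, which are not independent replicates, the log2 fold change in TH soleus correlated with gene GC effects estimated from 73 other libraries (r = 0.859). With the GC slope as a covariate 3380 genes were called, 11 oxidative phosphorylation and 6 macrophage genes rose, and none of the 4 named falls was called. Zfp729a and Trp53inp1 lay slightly above 0 in that fit. Without the covariate 11207 genes were called within males and 598 within females, and with it 3410 and 11. In females other fits called from 2 (only the groups compared) to 1215 (DESeq2).

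**Figure D3:**
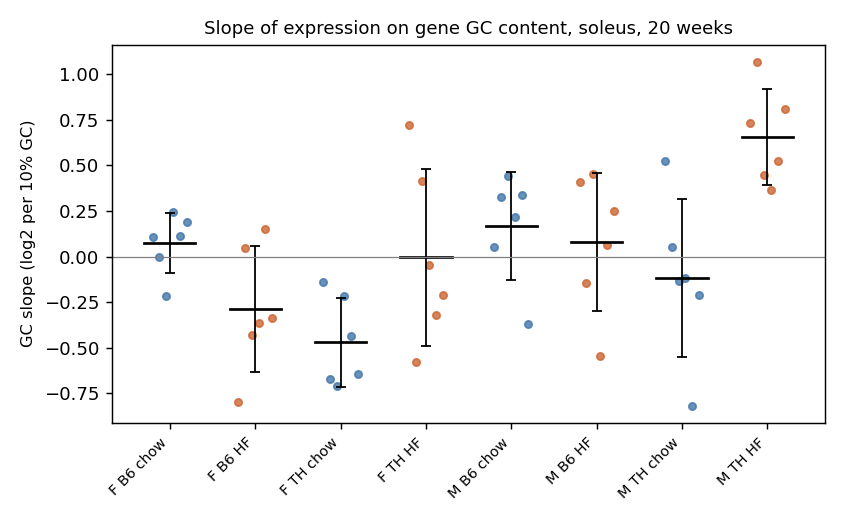
Slope of expression on gene GC content (log2 per 10% GC) in each soleus library at 20 weeks by sex, strain and diet, with mean and SD. High-fat TH males averaged 0.657 and chow TH males -0.117.

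The TH minus B6 difference in the soleus diet response was called for 11109 genes (5257 above 0, 5852 below) and for 788 with the GC slope as a covariate. Interferon-response genes had a lower TH than B6 response for 10 of 18 (1 GC), with Ifi44 (-3.39 ± 1.30) and Rsad2 (-2.07 ± 0.67), and oxidative phosphorylation genes a higher one for 31 of 42 (1 GC), with Cyc1 (0.96 ± 0.17). With the covariate Ifi44 (-1.32, adjusted p = 0.479) and Rsad2 (-0.50, adjusted p = 0.632) lost their calls. The muscle gene Mybph (3.30 ± 0.78) and the xenobiotic enzyme Cyp1a1 (2.29 ± 0.54) were among the highest, and called with the covariate too. For interferon response and oxidative phosphorylation genes the counts were 10 and 31 over the list alone, and camera gave adjusted p = 0.885 for each.

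The strain difference in soleus on chow differed between sexes for 14 genes. The lipase inhibitor Angptl4 (4.62 ± 0.83), a PPAR target, had a higher male than female difference and was the fatty acid oxidation gene called over all genes, 1 of 21 (0 groups only, 2 DESeq2/GC). Acoxl (2.17 ± 0.46) and the methyltransferase Mettl21c (1.68 ± 0.27) also lay above 0, and the cysteine dioxygenase Cdo1 (-2.42 ± 0.54) and the interferon regulator Irf5 (-1.79 ± 0.35) below. For fatty acid oxidation genes the count was 9 over the list alone, and camera gave adjusted p = 0.00194.

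At 5 weeks (11 TH and 12 B6 mice) fast-fibre genes were already lower in TH soleus, 11 of 14, with Myh1 (-1.27 ± 0.22) and Actn3 (-1.26 ± 0.36). Slow-fibre genes were higher for 6 of 12, with Myh7b (1.58 ± 0.20) and the slow troponin Tnnt1 (0.43 ± 0.11). Erythrocyte genes were lower for 5 of 6, with Alas2 (-1.66 ± 0.34), and interferon-response genes for 7 of 18 (13 GC), with Rsad2 (-1.76 ± 0.38). Of 3089 called genes (1457 higher, 1632 lower) B4galnt2 (7.65 ± 0.29), Opn1mw (6.67 ± 0.26) and Fam184b (4.45 ± 0.27) were highest and C1s1 (-8.54 ± 0.26), Eps8l1 (-4.88 ± 0.42) and Pttg1 (-4.80 ± 0.15) lowest in TH. With the GC slope as a covariate 4966 genes were called. For fast fibre, slow fibre, erythrocyte and interferon response genes the counts were 14, 9, 5 and 9 over the list alone, and camera gave adjusted p = 0.322, 0.322, 0.322 and 0.398.

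A week of high-fat feeding raised the fatty acid oxidation programme of soleus over both strains and sexes (26 high-fat, 23 chow): 17 of 21 genes rose. They included the thioesterases Acot1 (1.57 ± 0.18) and Acot2 (1.24 ± 0.14), Pdk4 (1.43 ± 0.20), the uncoupling protein Ucp3 (0.90 ± 0.15) and the carnitine transferase Cpt1b (0.44 ± 0.09). Among 396 called genes (315 up, 81 down) the nicotinic receptor gene Chrna2 (2.09 ± 0.25) rose most, and Depp1 (-0.85 ± 0.15), the mTOR inhibitor Ddit4 (-0.70 ± 0.14) and Unc13d (-0.66 ± 0.19) fell most. Unc13d was not called without replicate 1 or replicate 5 of the male TH chow group (adjusted p = 0.0658 and 0.0673). For fatty acid oxidation genes the count was 18 over the list alone, and camera gave adjusted p = 1.32e-09.

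Male soleus (12 mice) had lower slow-fibre transcripts than female soleus (12), 2 of 12 (4 DESeq2, 9 groups only), with Casq2 (-0.51 ± 0.08) and Myh7 (-0.40 ± 0.07) called. Of 318 called genes the Y-linked Ddx3y (7.83 ± 0.76), Eif2s3y (7.58 ± 0.63) and Kdm5d (6.64 ± 0.40) were highest and Xist (-8.93 ± 0.52), Armc2 (-1.31 ± 0.19) and Tecrl (-1.20 ± 0.29) lowest in males. With the GC slope as a covariate 1042 genes were called. For slow fibre genes the count was 9 over the list alone, and camera gave adjusted p = 0.0116.

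With age on chow (24 mice at 20 and 23 at 5 weeks) all 21 matrix genes fell in soleus, led by Col1a1 (-2.36 ± 0.19) and Timp1 (-2.25 ± 0.23), and 17 of 21 cell proliferation genes fell, led by Ccnb1 (-3.15 ± 0.41). Fatty acid oxidation genes rose for 17 of 21, with Acot1 (1.37 ± 0.18) and Pdk4 (1.26 ± 0.21). Interferon-response genes fell for 14 of 18, with Ifi44 (-2.53 ± 0.45). Of 8587 called genes Cyp1a1 (3.30 ± 0.37), Cdkl1 (2.70 ± 0.15) and the muscle hormone gene Ostn (2.56 ± 0.10) rose most and the fibrillin Fbn2 (-3.87 ± 0.25), keratocan Kera (-3.23 ± 0.26) and the noncoding Mirg (-3.20 ± 0.15) fell most. For extracellular matrix, cell proliferation, fatty acid oxidation and interferon response genes the counts were 21, 17, 17 and 14 over the list alone, and camera gave adjusted p = 0.0556, 0.375, 0.0556 and 0.407.

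Whole pancreas of TH (18 mice) and B6 (15) was compared on chow at 20 weeks. Beta cell genes were higher in TH for 6 of 16 and lower for 1 (11 no filter), with the insulin genes Ins1 (0.71 ± 0.20) and Ins2 (0.47 ± 0.19) and the transcription factor Mafa (1.72 ± 0.32) higher and Nkx2-2 (-1.65 ± 0.30) lower. Acinar genes, which encode digestive enzymes and their regulators, were higher for 9 of 21 and lower for 2 (7 trimmed), with Clps (0.50 ± 0.14) and Ctrb1 (0.48 ± 0.17) higher. Unfolded protein response genes were higher for 11 of 20, with Chac1 (1.00 ± 0.23) and Trib3 (0.96 ± 0.28). Interferon-response genes were lower for 8 of 14 (4 groups only), with Bst2 (-1.37 ± 0.14) and Rtp4 (-1.22 ± 0.40). None of the T cell genes passed the count filter in pancreas, so that list was not tested there. For beta cell, acinar, unfolded protein response and interferon response genes the counts were 6 higher and 1 lower, 11 higher and 2 lower, 11 and 9 over the list alone.

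Of 13367 pancreas genes 3631 were called, 1715 higher and 1916 lower in TH, 512 by at least 2-fold. TH excesses were largest for the ephrin receptor Epha8 (7.23 ± 0.26), the chimaerin Chn2 (5.63 ± 0.31), chymotrypsin C Ctrc (4.22 ± 0.14), the complement gene C1qa (4.22 ± 0.16) and Thsd4 (3.62 ± 0.15). Deficits were largest for Clic6 (-8.42 ± 0.39), C1s1 (-7.06 ± 0.27), the trypsinogen Prss3 (-6.25 ± 0.36), Camk2b (-6.19 ± 0.17) and Dusp26 (-5.57 ± 0.17). Trypsinogen genes are close paralogs, so the Prss3 value depends on read assignment. Without 1 deviating library, replicate 4 of the female TH chow group, Ins2 and Ctrb1 were not called (adjusted p = 0.0519 and 0.0508).

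In B6 pancreas 16 weeks of high-fat diet (14 high-fat, 15 chow) changed 206 genes, 112 up and 94 down. The fuel-switch kinase Pdk4 (2.10 ± 0.60, adjusted p = 0.0424), the FGF-responsive factor Etv5 (1.86 ± 0.30), the serotonin transporter Slc6a4 (1.60 ± 0.19) and Ugt2b34 (1.34 ± 0.15) rose. The threonine dehydrogenase Tdh (-2.48 ± 0.26), Trim50 (-1.41 ± 0.23), the placental growth factor Pgf (-1.23 ± 0.26) and the hormone gene Fgf21 (-1.12 ± 0.27) fell.

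In TH pancreas (13 high-fat, 18 chow) the islet hormone list of alpha, delta and PP cells rose for 4 of 7 (1 groups only), with pancreatic polypeptide Ppy (1.23 ± 0.34), Pyy (1.03 ± 0.27) and glucagon Gcg (0.52 ± 0.11). Unfolded protein response genes rose for 10 of 20 (4 groups only/GC), with Pdia4 (0.63 ± 0.17) and Hspa5 (0.41 ± 0.12). Of the Reg and acute stress genes 1 of 8 rose and 2 fell (6 no filter), Reg3g (1.54 ± 0.47) up and Reg2 (-2.56 ± 0.58) and Reg3d (-1.15 ± 0.25) down. Of the ductal genes 3 of 11 rose and 2 fell (3 block), Spp1 (0.48 ± 0.09) up and Krt19 (-0.77 ± 0.16) down. Of the beta cell genes the amylin gene Iapp (0.73 ± 0.17) rose and Mafa (-1.002 ± 0.33) fell, 1 and 1 of 16 (1 RLE/block/groups only/DESeq2/GC). For alpha, delta and PP cell and unfolded protein response genes the counts were 5 and 12 over the list alone, and camera gave adjusted p = 0.0140 and 0.180. For Reg and acute pancreatic stress, ductal and beta cell genes they were 1 up and 3 down, 4 up and 2 down and 1 up and 2 down over the list alone.

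Of 758 called genes (313 up, 445 down) Pdk4 (2.67 ± 0.54), Etv5 (2.51 ± 0.26), Ugt2b34 (1.72 ± 0.20) and Tpm2 (1.62 ± 0.37) were among the largest rises. Tdh (-4.98 ± 0.68), Clec11a (-2.82 ± 0.24), Trim50 (-2.64 ± 0.27), Reg2 and the neuropeptide gene Gal (-2.15 ± 0.20) fell most. Within males 1276 genes were called (775 with the replicate block, 514 in a fit of only the groups compared, 800 with the GC slope) and within females 44 (202 with no filter on low counts). High-fat TH males had a median total of 2415506 reads against 6415007.5 on chow. With the GC slope as a covariate 489 genes were called, and 4 unfolded protein response genes rose.

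**Figure D4:**
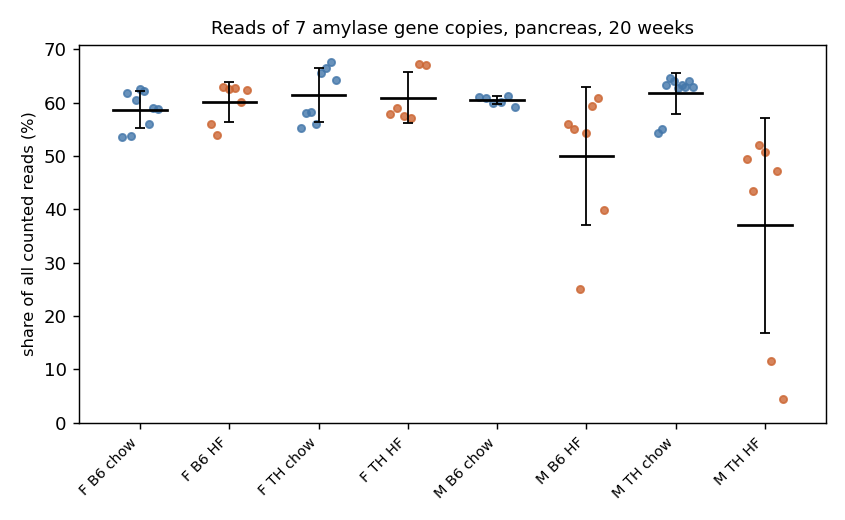
Share of counted reads (%) from 7 amylase gene copies in each pancreas library at 20 weeks by sex, strain and diet, with mean and SD. High-fat TH males ranged from 4.39% to 52.0%.

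The TH minus B6 difference in the pancreas diet response was called for 151 genes (75 above 0, 76 below). Glucagon Gcg (0.61 ± 0.16) was the alpha, delta and PP cell gene called, 1 of 7 (0 groups only/GC). Tpst1 (1.14 ± 0.28), Tubb2a (1.10 ± 0.28) and the glutamate receptor Gria3 (1.02 ± 0.24) lay highest and Clec11a (-2.04 ± 0.39), Gal (-1.78 ± 0.25) and Arhgef19 (-1.47 ± 0.21) lowest. Fits of only the groups compared and with the GC slope called 37 and 76 genes, and neither called Gcg. For alpha, delta and PP cell genes the count was 2 over the list alone, and camera gave adjusted p = 0.411.

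The male minus female strain difference in pancreas was called for 193 genes. Unfolded protein response genes lay below 0 for 7 of 20 (1 GC, 3 block), with Creld2 (-1.17 ± 0.30) and Hspa5 (-0.98 ± 0.23). Prss3 (2.28 ± 0.62) was among the highest and Hist1h1c (-1.69 ± 0.32) among the lowest. With the GC slope as a covariate 19 genes were called, 1 of them of the unfolded protein response, but neither Creld2 nor Hspa5. Without replicate 4 of the female TH chow group Creld2 and Prss3 were not called (adjusted p = 0.0540 and 0.0540). For unfolded protein response genes the count was 9 over the list alone, and camera gave adjusted p = 0.183.

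At 5 weeks (13 TH, 12 B6) unfolded protein response genes were higher in TH pancreas for 15 of 20, with Chac1 (1.19 ± 0.26) and Pdia4 (1.07 ± 0.18), and cell proliferation genes for 11 of 21, with Cdc20 (1.09 ± 0.29) and Mki67 (0.87 ± 0.25). Ductal genes were lower for 5 of 11, with Spp1 (-1.36 ± 0.09) and Krt19 (-0.87 ± 0.16). Of the circadian clock genes 3 of 15 were higher and 6 lower, with Nr1d1 (-1.97 ± 0.32) lower and Cry1 (0.86 ± 0.24) higher. Of 3397 called genes (1680 higher, 1717 lower) Epha8 (6.96 ± 0.30), Chn2 (4.31 ± 0.26) and Ctrc (4.04 ± 0.15) were highest and Clic6 (-6.72 ± 0.41), C1s1 (-6.50 ± 0.27) and Camk2b (-5.96 ± 0.20) lowest. For unfolded protein response, cell proliferation and ductal genes the counts were 16, 14 and 5 over the list alone, and camera gave adjusted p = 0.511, 0.698 and 0.00160. For circadian clock genes it was 3 higher and 8 lower over the list alone.

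A week of high-fat feeding lowered digestive-enzyme and Reg transcripts in pancreas over both strains and sexes (25 high-fat, 25 chow). Reg and acute stress genes fell for 7 of 8, led by the injury-responsive Reg3a (-3.86 ± 0.49) and Reg3b (-3.21 ± 0.41). Acinar genes fell for 15 of 21, with Ctrb1 (-0.67 ± 0.13) and Cela1 (-0.50 ± 0.13). Mature adipocyte genes rose for 4 of 13 (8 no filter), with Adipoq (0.82 ± 0.25), beta cell genes for 3 of 16 (8 groups only), with Iapp (0.65 ± 0.13) and G6pc2 (0.83 ± 0.16), and cell proliferation genes for 8 of 21 (4 DESeq2), with Ube2c (0.88 ± 0.20). All 6 erythrocyte genes fell. Of 738 called genes (312 up, 426 down) Nxph2 (1.68 ± 0.15), Zbtb16 (1.30 ± 0.35) and Etv5 (1.28 ± 0.19) rose most and Prss3 (-2.80 ± 0.25) fell beside the Reg genes. For Reg and acute pancreatic stress, acinar, mature adipocyte, beta cell, cell proliferation and erythrocyte genes the counts were 8, 17, 11, 6, 10 and 6 over the list alone, and camera gave adjusted p = 1.71e-04, 0.0688, 0.0554, 0.326, 0.326 and 0.160.

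Male (16 mice) and female (17) pancreas differed in 98 genes. Glucagon Gcg (-0.49 ± 0.11) was lower in males, 1 of 7 alpha, delta and PP cell genes, and the immediate early gene Jun (0.82 ± 0.22) higher, 1 of 7 (0 RLE/block/DESeq2, 4 no filter). Jun was not called with RLE factors, the replicate block, DESeq2 or only the groups compared. The Y-linked Eif2s3y (8.98 ± 0.23), Ddx3y (8.83 ± 0.26) and Kdm5d (7.99 ± 0.30) were highest and Xist (-9.37 ± 0.24), the uridine phosphorylase Upp2 (-1.37 ± 0.27) and Cdhr2 (-0.99 ± 0.15) lowest. For immediate early genes the count was 4 over the list alone, and camera gave adjusted p = 0.221. For alpha, delta and PP cell genes it was 1 over the list alone.

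From 5 to 20 weeks on chow (25 and 33 mice) all 21 cell proliferation genes fell in pancreas, with Mki67 (-3.13 ± 0.21) and Ccnb1 (-3.42 ± 0.38), and 19 of 20 matrix genes fell, with Postn (-2.37 ± 0.13) and Col3a1 (-2.19 ± 0.08). Acinar genes rose for 16 of 21, with Clps (0.57 ± 0.11) and Ctrl (0.57 ± 0.10). Of the Reg and acute stress genes 5 of 8 fell, led by Reg3a (-4.59 ± 0.48), Reg3g (-3.78 ± 0.31) and Reg3b (-3.49 ± 0.39). Of 4021 called genes Cobl (3.19 ± 0.15), the osteocalcin-related Bglap3 (2.69 ± 0.15) and Shank1 (2.44 ± 0.17) rose most. For cell proliferation, extracellular matrix, acinar and Reg and acute pancreatic stress genes the counts were 21, 20, 18 and 5 over the list alone, and camera gave adjusted p = 0.00122, 2.35e-10, 0.321 and 0.321.

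Strain calls on chow at 20 weeks were set side by side over the 12485 genes tested in all 4 tissues. TH exceeded B6 in all 4 tissues for 173 genes and lay below it in all 4 for 223, where independent lists would share 13.7 and 10.7. Fat, liver and soleus came in part from the same mice, so these lists are not independent samples. Genes with large mean differences were named after their values were seen. C1s1 (-8.88 ± 0.23 in liver, -8.02 ± 0.21 in fat, -8.02 ± 0.24 in soleus, -7.06 ± 0.27 in pancreas) lay lowest, and Pcp4l1 (-4.39 ± 0.30 in liver, -4.78 ± 0.37 in fat, -4.84 ± 0.18 in soleus, -5.08 ± 0.61 in pancreas) and Eps8l1 (-5.28 ± 0.49 in liver, -3.79 ± 0.43 in fat, -5.67 ± 0.43 in soleus, -2.05 ± 0.38 in pancreas) were among the lowest. Ifi202b (5.97 ± 0.75 in liver, 8.32 ± 0.39 in fat, 5.78 ± 1.06 in soleus, 5.32 ± 0.57 in pancreas) lay highest, an interferon-inducible DNA sensor family member with near-identical copies, and Pianp (2.28 ± 0.19 in liver, 3.01 ± 0.18 in fat, 3.50 ± 0.18 in soleus, 2.52 ± 0.36 in pancreas) was among the highest. The fold differed between tissues for 100 of the genes higher and 132 of those lower in TH (heterogeneity test over the 4 tissue estimates, Benjamini-Hochberg adjusted over the shared genes).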

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

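The tests of explanations, counts within a sex, diet by sex in TH and other splits of the samples were chosen or read only after the results were seen. Of 17 group values examined for a sample far from the rest, 3 held one, where chance gives about 1 in 20. In fat at 20 weeks replicate 2 of the chow TH males had 1497 CPM of Gpnmb and its nearest neighbour 633.8, and replicate 1 of the chow TH females 44.01 and its nearest 12.37. In liver replicate 1 of the chow TH males had 2.531 CPM of Col1a1 and its nearest 4.791. All 6 chow TH males lay above the 6 chow B6 males for Gpnmb.

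Tested directly, the diet response was called different between strains for 677 genes in liver, 85 in fat, 11109 in soleus and 151 in pancreas. Alternative fits called from 443 to 786 in liver, 24 to 275 in fat, 788 (GC slope) to 11586 in soleus and 37 to 305 in pancreas. Named log2 differences, TH minus B6, in liver were Fam198a (3.61), Vnn1 (2.61), Prom1 (2.56), Pdk4 (2.37), Scd1 (1.55), Cd36 (1.45), Col1a1 (1.45), Acacb (1.44), Col1a2 (1.08), Bmf (-1.73), Kcnk10 (-1.76) and Ly6a (-3.18). In fat they were Dpp6 (5.21), Cyp2f2 (2.44), Mamld1 (1.10), Mest (-1.87), Sfrp5 (-2.06), Mug1 (-3.76), Apoa1 (-3.76) and Mup20 (-4.001), but Dpp6, Mamld1 and Sfrp5 not without deviating libraries. In soleus they were Mybph (3.30), Cyp1a1 (2.29), Cyc1 (0.96), Rsad2 (-2.07) and Ifi44 (-3.39), but Rsad2 and Ifi44 not with the GC slope. In pancreas they were Tpst1 (1.14), Tubb2a (1.10), Gria3 (1.02), Gcg (0.61), Arhgef19 (-1.47), Gal (-1.78) and Clec11a (-2.04), but Gcg not with the GC slope or only the groups compared. The strain difference on chow differed between the sexes for 851 genes in liver, 321 in fat, 14 in soleus and 193 in pancreas. Male minus female values in liver were Mt2 (4.66), Rad51b (4.60), Npas2 (4.15), Manf (-1.13), Hyou1 (-1.21), Cyp4a12a (-2.90), Hsd3b5 (-3.18), Susd4 (-3.21), Nat8f6 (-3.86) and Ugt2b37 (-4.97). Those in fat were Atp6v0d2 (7.00), Mup18 (6.43), Gpnmb (4.95), Itgax (3.80), Ms4a1 (-2.92), Cxcl13 (-2.95) and Fosb (-3.10). Those in soleus were Angptl4 (4.62), Acoxl (2.17), Mettl21c (1.68), Irf5 (-1.79) and Cdo1 (-2.42), but Angptl4 not with only the groups compared. Those in pancreas were Prss3 (2.28), Hspa5 (-0.98), Creld2 (-1.17) and Hist1h1c (-1.69), but Creld2 and Hspa5 not with the GC slope, nor Creld2 and Prss3 without deviating libraries.

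The diet response of TH liver at 20 weeks differed between males and females for 719 genes. The male response exceeded the female one for 11 of 23 fatty acid oxidation genes, including the microsomal hydroxylases Cyp4a14 (3.71 ± 0.93) and Cyp4a10 (3.10 ± 0.58). It did so for 5 of 12 lipid droplet genes, led by Cd36 (4.14 ± 0.48) and Pparg (2.83 ± 0.74), and for 7 of 20 matrix genes (2 groups only), led by Col1a1 (2.03 ± 0.47). Within males Cd36 rose (2.18 ± 0.35), and within females it fell (-1.96 ± 0.33). For fatty acid oxidation, lipid droplet and extracellular matrix genes the counts were 17, 5 and 11 over the list alone, and camera gave adjusted p = 0.0312, 0.00570 and 0.115 (estimated correlation).

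In pancreas the same test called 99 genes. The male response exceeded the female one for 4 of 8 Reg and acute stress genes (1 GC, 2 block), including Reg3a (7.08 ± 1.72) and Reg3g (3.59 ± 0.94), and lay below it for 3 of 16 beta cell genes (0 groups only, 7 no filter), the transcription factor Nkx6-1 (-2.90 ± 0.66), the zinc transporter Slc30a8 (-2.24 ± 0.48) and the glucose transporter Slc2a2 (-1.35 ± 0.31). In fat it called 1 gene, the kinase-like receptor gene Ryk (0.65 ± 0.10), and in soleus 2, Phlda1 (1.68 ± 0.29) and Cd209g (2.17 ± 0.45), named after their values were seen. For Reg and acute pancreatic stress and beta cell genes the counts were 6 and 4 over the list alone, and camera gave adjusted p = 0.0313 and 0.0568 (estimated correlation).

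The number of genes called for diet in TH soleus followed transcript GC content. Of the called genes 96.5% had the sign of the GC effect estimated from libraries outside the contrast, so a GC trend between libraries may have made most of the calls. With each library's GC slope in the model 3380 genes were called, 2507 of them also without it with the same sign. A linear slope can leave part of that trend, so it stays open for these too. A difference in library size is argued against by median totals whose ratio was 0.875. Diet itself and RNA or library handling that went with the group stay open, since no batch is labelled.

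Genes called by strain in all 4 tissues could reflect TH variants that cost reads against a B6-based reference genome. The fold differed between tissues for 109 lower and 65 higher genes that neither are pseudogenes nor have one of their name. In a simulation of 1000 sets of equal folds the test of that difference called 28. Transcript forms can differ by tissue, so lost reads need not give equal folds. For these, and the other 114 lower and 108 higher genes, lost reads and genetic regulation in TH cannot be told apart. Of the 108, 69 are annotated pseudogenes, and no variants were analysed here.

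Of the 16 beta cell genes 5 fell in high-fat TH males (Mafa (-2.13 ± 0.46), Nkx6-1 (-1.998 ± 0.46), Slc30a8, Ucn3 and Slc2a2), with a median of -1.59. The insulin genes showed no such fall (-0.007 ± 0.27 for Ins1, -0.05 ± 0.26 for Ins2). The 5 were picked for falling and insulin per cell was not measured, so a lower beta cell share stays open. The high-fat males had lower totals. A fit of the TH groups alone called 3 of the 5 (median -1.47). With every male library thinned to the lowest male total, 2138387 reads, the median was -1.40 and each of the 5 was called in at most 5 of 20 draws. Between these fits Mafa went from -1.96 ± 0.57 to -1.73 ± 0.62, Nkx6-1 from -1.89 ± 0.52 to -1.51 ± 0.64 and Slc30a8 from -1.47 ± 0.37 to -1.40 ± 0.48. The calls ended with wider errors at folds that moved by less than those errors. With so few calls left, depth and a diet effect on these genes cannot be told apart. A change within the beta cells of these diabetes-prone males remains a hypothesis.

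For each contrast 40 splits of its samples, the real one included, were refitted alone, which gives other counts than the reported fits. In 33 of 40 contrasts no other split called as many genes (1 of 40, the lowest share that 40 splits can give). Unadjusted over the contrasts, this share does not exclude chance for each. Interaction splits redrew diet or sex and so mixed main effects too, and decide nothing. The real count and the highest other count follow. In liver these were strain at 20 weeks 6196 and 2570, diet in B6 3185 and 137, diet in TH 4256 and 2020, strain by diet 578 and 1, strain by sex 283 and 108, strain at 5 weeks 6662 and 3, diet at 5 weeks 4224 and 1, sex 6562 and 0, age 3429 and 0 and diet by sex in TH 390 and 101. In fat these were strain at 20 weeks 5598 and 1179, diet in B6 565 and 1, strain by diet 41 and 25, strain by sex 1012 and 139, strain at 5 weeks 3315 and 620, sex 3154 and 13 and age 5418 and 530. In soleus these were strain at 20 weeks 9746 and 5771, diet in TH 11839 and 8321, strain by diet 11586 and 0, strain by sex 18 and 3, strain at 5 weeks 2784 and 1797, diet at 5 weeks 221 and 1, sex 827 and 0 and age 8984 and 5662. In pancreas these were strain at 20 weeks 3028 and 0, diet in B6 164 and 1, diet in TH 360 and 32, strain by sex 70 and 18, strain at 5 weeks 3328 and 128, diet at 5 weeks 1047 and 1, age 3743 and 8 and diet by sex in TH 28 and 1. At least 1 other split called as many genes for fat diet in TH (119 genes, 2 splits as large, highest other 126) and fat diet at 5 weeks (9, 4, 2752). The same held for fat diet by sex in TH (4, 4, 125) and soleus diet in B6 (123, 3, 1915). It also held for pancreas strain by diet (37, 2, 162) and pancreas sex (95, 2, 1098). For soleus diet by sex in TH the fit called 0 genes by edgeR, 1531 at an unadjusted p under 0.05, so its splits decide nothing (highest other 3424). Other splits with several times the real count, as in fat, soleus and pancreas, point to a structure of the samples beyond the compared groups.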

How the results depend on the processing

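The alternatives so marked above and the contrast of diet by sex in TH were chosen after the data were seen. With RLE factors all 42 counts stayed within 1.5 times, and leaving out each of the 5 mice of the male TH chow group at 5 weeks left all 15 soleus counts it touched within that range. The number of genes called by strain in all 4 tissues stayed within it under each of 7 alternatives, from 362 to 534 around 396. The label check counted libraries against a fixed marker, so that no alternative applied. Of 467 named gene values, which leave out genes dropped after losing it, the call was lost for 4 with RLE factors, 5 with DESeq2, 15 with the replicate block, 19 with the GC slope and 25 with no filter on low counts. It was lost for 34 of 440 in fits of only the groups compared and for 17 of 325 without deviating libraries, and for 19 of 116 in fat with neighbouring tissue scores. In soleus 2 values, diet in TH for Trp53inp1 (0.05) and Zfp729a (0.10), took the other sign with the GC slope, neither called. Pancreas libraries had the lowest median total of the 4 tissues.

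Counts per contrast that moved by over 1.5 times follow, as reported and under the alternative. Why a count moved was not tested. Numbers with an exponent are rounded to 2 digits. With no filter on low counts, which adds genes to the adjustment, they were, in liver strain by diet 677 to 443, strain by sex 851 to 552, diet by sex in TH 719 to 449, in fat diet in TH 39 to 15, strain by sex 321 to 171, diet by sex in TH 1 to 2, in soleus diet in B6 23 to 4, diet at 5 weeks 396 to 2.2e+02, sex 318 to 210, diet by sex in TH 2 to 1, and in pancreas diet in B6 206 to 385, strain by diet 151 to 305, strain by sex 193 to 336, sex 98 to 2.4e+02, diet by sex in TH 99 to 275. In fits of only the groups compared, which hold fewer libraries, they were, in liver strain by sex 851 to 283, diet by sex in TH 719 to 390, in fat diet in TH 39 to 119, strain by diet 85 to 41, strain by sex 321 to 1012, diet at 5 weeks 15 to 9, diet by sex in TH 1 to 4, in soleus diet in B6 23 to 123, diet at 5 weeks 396 to 221, sex 318 to 827, diet by sex in TH 2 to 0 (1531 at an unadjusted p under 0.05 by edgeR), and in pancreas diet in TH 758 to 360, strain by diet 151 to 37, strain by sex 193 to 70, diet by sex in TH 99 to 28. DESeq2 gave, in fat diet in TH 39 to 174, strain by diet 85 to 275, strain by sex 321 to 511, diet at 5 weeks 15 to 78, diet by sex in TH 1 to 58, and in soleus diet in B6 23 to 37, strain by sex 14 to 32, diet by sex in TH 2 to 1. The GC slope as a covariate gave, in liver sex 7684 to 4564, in fat diet in B6 592 to 902, diet in TH 39 to 84, in soleus strain on chow at 20 weeks 8725 to 5238, diet in B6 23 to 50, diet in TH 11917 to 3380, strain by diet 11109 to 788, strain by sex 14 to 65, strain at 5 weeks 3089 to 4966, diet at 5 weeks 396 to 1065, sex 318 to 1042, diet by sex in TH 2 to 6, and in pancreas diet in TH 758 to 489, strain by diet 151 to 76, strain by sex 193 to 19. Without deviating libraries the counts were, in fat diet in TH 39 to 145, strain by diet 85 to 49, strain by sex 321 to 1162, diet at 5 weeks 15 to 38, diet by sex in TH 1 to 17, and in soleus diet by sex in TH 2 to 1. Neighbouring tissue scores as covariates gave, in fat diet in TH 39 to 1.0e+02, strain by diet 85 to 24, diet at 5 weeks 15 to 25, diet by sex in TH 1 to 2.

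Under the GC slope, only the groups compared, no filter on low counts, the replicate block, DESeq2 and RLE factors, in that order, 6, 8, 6, 3, 2 and 0 of 24 counts within a sex and 21, 17, 12, 5, 10 and 2 of 130 counts of list members (129 with only the groups compared) moved by over 1.5 times. Without deviating libraries these were 5 of 18 and 10 of 86, and with neighbouring tissue scores 2 of 6 and 8 of 35.

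Replicate numbers did not pair the samples: deviations from the group mean correlated at a median r of 0.00901 in liver, 0.00167 in fat, 0.00982 in soleus and 0.00571 in pancreas for libraries with one number, across genes, which are not independent replicates. With the number as a block the counts moved by over 1.5 times in soleus diet by sex in TH 2 to 1, and in pancreas diet in TH 758 to 466, strain by sex 193 to 32, diet by sex in TH 99 to 58, and for no other contrast.

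Of 558 list tests camera called 233 with the preset correlation and 17 with an estimated one. Those held in liver were fatty acid synthesis for diet in TH, cholesterol synthesis for diet at 5 weeks, both sex-biased lists for sex, and matrix for age. In fat they were interferon response for diet at 5 weeks and T cell and B and plasma cell for age. In soleus they were interferon response for diet in B6, fatty acid oxidation for strain by sex and diet at 5 weeks, and slow fibre for sex. In pancreas they were alpha, delta and PP cell for diet in TH, ductal for strain and Reg for diet at 5 weeks, and matrix and cell proliferation for age.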

Other observations

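Gene values within TH males were looked at only after the contrasts over both sexes. In male TH fat the 20-week diet lowered 4 of 15 mature adipocyte genes, with adipsin Cfd (-2.54 ± 0.40), resistin Retn (-1.25 ± 0.33) and the insulin-regulated glucose transporter Slc2a4 (-0.90 ± 0.26), and 4 of 6 erythrocyte genes, with Alas2 (-1.37 ± 0.40) (edgeR, 6 high-fat and 6 chow mice). In females Cfd stood at -0.16 ± 0.37, adjusted p = 1.00, and the difference between the sexes was called for 1 gene in fat. Epididymis markers rose in the same male libraries for 11 of 14, such as Crisp1 (7.39 ± 1.47), but the list mean reached 9.34 and 8.53 log2 CPM in replicates 1 and 3 and at most 0.511 in the other 4. In male TH soleus the uncorrected fit called 12 of 18 macrophage and 5 of 6 erythrocyte genes higher, with medians of 0.99 and 1.39 in males and 0.36 and 0.72 in females.

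In pancreas the 7 amylase copies took 37% ± 20.1 of the counted reads in high-fat TH males (SD, n = 7). On chow they took 61.7% ± 3.79 (SD, n = 10; two-sided exact permutation p = 5.14e-05, adjusted over 4 comparisons 2.06e-04). All 7 lay below the lowest chow mouse. Chow TH male replicates 1 and 2 held at most 54.98%, 3 to 10 at least 62.8%. The test ignores such unlabelled subsets (also in TH females), which were not separated from diet. In B6 males the shares were 50% ± 13 (SD, n = 7) and 60.4% ± 0.758 (SD, n = 6; exact p = 0.0321, adjusted 0.0642, which misses the threshold). In females the exact p was 0.911 in TH, with means of 60.9% and 61.4%, and 0.434 in B6, with 60.1% and 58.7%. Whether the diet effect differed between sexes was not tested, and the near-identical copies were summed.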
